A study of Mus musculus with 18 samples.

How the data were processed

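Gene expression was measured by sequencing of total RNA from whole uterus homogenate of mice, extracted with Trizol and made into libraries with a TruSeq total RNA kit, per the labels. The deposited table holds 1 raw count per gene symbol and library, for 22238 symbols and 18 libraries. Per the submitters' processing notes the tools were Trimmomatic 0.36, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.6, StringTie 1.3.4d, DESeq2 1.18.1 and R 3.4.4 with build GRCm38. Which tool made the counts, the annotation, the strand setting, the handling of reads that map to several places, the doses and the times are not given in the sources used here. The values were checked to be whole numbers of at least 0, and 2904 symbols had a count of 0 in all libraries. No pair of libraries from the same group was a copy of another, with a chi-square per degree of freedom of 15.7 to 69.4 between them over genes with at least 20 counts.

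Libraries were grouped by the DOX and hormone labels into 6 groups of 3. Genes with low counts were removed with filterByExpr of edgeR 4.0.16, which left 15494 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model of edgeR with robust dispersion was fitted to the 6 groups at once, with 12 residual degrees of freedom, and each comparison was a contrast of that model tested with its F test. P-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05, and the count of genes that also changed at least 2-fold was kept. The SE of a log2 fold change was its value divided by the square root of F. CPM values are counts scaled by the TMM library sizes. The 10 comparisons were DOX against PBS under OIL, E2 and P4 and averaged over these, E2 and P4 against OIL in each arm, and the interaction of each hormone with DOX. The tests, the lists, the rule for naming genes and the alternatives, except those named below as added, were set before the data were examined. Which lists the text describes was chosen with the results in view.

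The slope of the DOX arm on the PBS arm was a regression through the origin across genes called in the PBS arm, with an error from a jackknife over libraries. Choosing genes on the PBS arm pulls the slope down, so genes chosen on the DOX arm were used as well. Fixed lists of genes, 47 in number with 1036 entries, of which 26 were matched by an older symbol and 16 were not in the table, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run as checks, and with the estimated correlation 0 lists passed in each of the 10 comparisons, against 107 list calls with the preset value. Fry, which does not compare members with other genes, called 17 lists for DOX under E2 and 8 for DOX averaged. It called 20 and 29 for E2 under PBS and DOX, 14 and 15 for P4, and 7 for the E2 by DOX interaction. For DOX under OIL, DOX under P4 and the P4 by DOX interaction it called 0. Members were counted by the edgeR test over all genes and adjusted over the list alone. These counts are to be read against the share of all tested genes called in the comparison. That share was 41.04% for DOX under E2, 18.63% for DOX averaged and 22.93% for the E2 by DOX interaction. It was 61.44% and 72.63% for E2 under PBS and DOX, and 31.82% and 29.81% for P4.

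In the main comparisons the text names the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 1, a symbol that is not a clone or predicted name, and groups that do not overlap in CPM (overlap was not asked of the interactions). It names the 3 largest each way in the other comparisons, up to 4 members with the smallest p of each list described, and 12 genes in every comparison. Some results that fall under this rule are not reported. Principal components were computed on log2 CPM of the 1000 most variable genes. Positions come from GENCODE M21.

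Alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, limma voom with quality weights, no filter, a stricter filter (at least 1 CPM in at least 3 libraries), a fit of only the groups compared, the replicate number as a block, removal of mitochondrial and small RNA features, and leaving out each library in turn. An adipocyte score as a covariate and a correction for GC content and transcript length in 20 bins, which covered 98.55% of the tested genes, were added after the data were seen. For each comparison the libraries were also split in the other ways that keep the group sizes, with 100 splits drawn by a fixed seed where there were more.

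The pipeline was tested on simulated data made from these counts. Of the genes changed 1.5-fold, 2-fold and 4-fold it recovered 44.78%, 64.18% and 93.94% under OIL, 35.82%, 64.18% and 96.97% under E2, 43.28%, 79.1% and 87.88% under P4, and 15.15%, 44.78% and 83.33% in the E2 by DOX interaction. False calls were 6 of 141, 3 of 134, 6 of 146 and 0 of 95. A simulated list was called, with 0 other lists. Each gene was drawn independently of the others there, so this does not measure false list calls in the real libraries. Other splits of those libraries called up to 24 lists with the preset correlation. The software was R 4.3.3, Python 3.11.15 and matplotlib 3.10.9.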

Results

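Total RNA of whole mouse uterus was sequenced from ovariectomized adult CD-1 animals, an outbred stock, given doxorubicin (DOX, an anthracycline that poisons topoisomerase II) or phosphate-buffered saline (PBS, the vehicle). Within each arm the animals received oil (OIL), estradiol (E2) or progesterone (P4), which makes 6 groups of 3 libraries each. The libraries held between 18042357 and 39783785 counts. The highest was PBS E2 replicate 1, and the next was DOX E2 replicate 3 with 28122299. The labels give no dose, no time of collection and no statement that the samples are separate animals, so p-values measure the spread between these samples. The question the series names is how DOX alters the uterine response to estrogen, and each comparison below is a part of it. Positions on mouse build GRCm38 follow GENCODE M21: Cdkn1a lies on chromosome 17 at 29090976 to 29100727, Mdm2 on 10 at 117688875 to 117710758, Esr1 on 10 at 4611593 to 5005614, Igf1 on 10 at 87858265 to 87937042, Cxcl10 on 5 at 92346638 to 92348889, Rfx2 on 17 at 56775897 to 56831013, Ddit4 on 10 at 59949669 to 59951834, Kcnh1 on 1 at 192190774 to 192510159, Slc6a14 on X at 21714896 to 21742355 and Areg on 5 at 91139599 to 91148432. Floors given for undetected genes cover counting error only.

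The main axis of variation parted the E2 libraries from the rest. The first component held 62.9% of the variance of the 1000 most variable genes and placed the DOX E2 libraries between 71.5 and 75.6, the PBS E2 libraries between 24.6 and 49.4, and the other 12 below 0. The second component held 16.2% and placed the P4 libraries, 15.5 to 31.1, above the OIL libraries, -32.6 to -14.9. On the second component the DOX OIL libraries, -19.3 to -14.9, lay above the PBS OIL libraries, -32.6 to -20.7. On both components the DOX and PBS libraries of P4 overlapped.

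**Figure D1:**
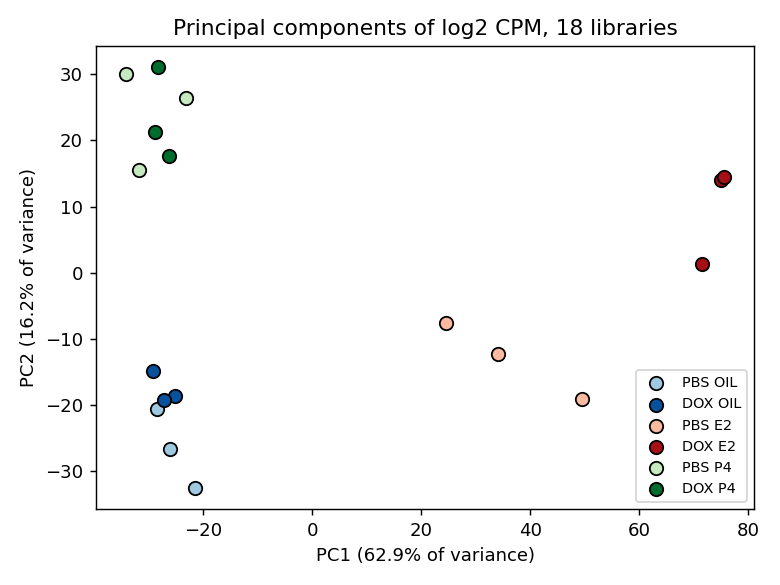
Principal components of log2 CPM, 1 point per library, colored by group (3 libraries each); the x axis is the first component with 62.9% of the variance and the y axis the second with 16.2%. The 3 DOX E2 libraries lie at 71.5 to 75.6 on the first component, to the right of the 3 PBS E2 libraries at 24.6 to 49.4.

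In the absence of hormone, DOX changed 2 of 15494 genes. Rfx2, a transcription factor of cilia formation, rose by 0.95 ± 0.14 on the log2 scale (SE, n = 3 per group), from 31.03 ± 6.15 to 59.9 ± 3.41 CPM (counts scaled by library size, SD). Ddit4, an inhibitor of mTORC1 induced by stress, fell by 1.32 ± 0.2, from 48.8 ± 7.92 to 19.5 ± 1.55 CPM. Both had an adjusted p of 0.047. The Rfx2 call ended in 5 of the 6 fits that left out 1 library of these groups (all but PBS OIL replicate 2; 0.86 to 1.12) and the Ddit4 call in all 6 (-1.44 to -1.2). At an unadjusted p under 0.05 there were 1253 genes. DESeq2 called 20 and limma voom 1. Both edgeR calls also ended with the replicate block, with the adipocyte covariate and with the GC and length correction.

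Transcripts that mark p53 activity and interferon signalling lay higher under OIL without passing the test over all genes. Of the 34 measured interferon-stimulated genes, 0 passed over all genes and 2 rose when adjusted over the list alone, with a median log2 fold change of 0.65. Cxcl10, a chemokine induced by interferon gamma, was at 2.36 ± 0.45 and Bst2 at 0.52 ± 0.14. Of the 30 p53 targets 0 passed over all genes and 3 rose when adjusted over the list alone: Zmat3 (0.9 ± 0.16), Eda2r (0.82 ± 0.19) and Ccng1 (0.54 ± 0.13). Cdkn1a, the cell cycle inhibitor p21, was at 1.05 ± 0.34 and Mdm2, which encodes the ligase that degrades p53, at 0.06 ± 0.1. Without PBS OIL replicate 2, Zmat3 passed over all genes (1.1 ± 0.16). The camera test with its preset correlation called the interferon list (adjusted p = 1.97e-15) and the p53 list (0.000126) higher. With an estimated correlation the adjusted p was 0.924 for both. Adipocyte markers, genes of fat cells, lay lower. Their median was -1.71 with 0 of 21 members passing over all genes or adjusted over the list alone (preset adjusted p = 3.5e-05; adjusted p = 0.924 with an estimated correlation). The preset correlation called 4 more lists under OIL, with 0 members passing over all genes or adjusted over the list alone. Smooth muscle markers (adjusted p = 3.78e-05, or 0.467 without DOX OIL replicate 3; Synpo2 at 0.83 ± 0.29) and mitochondrially encoded genes (0.00871, or 0.0515 without PBS OIL replicate 3 and 0.0646 without DOX OIL replicate 2) lay higher. B and plasma cell markers (0.000902; Pax5 at -1.86 ± 0.96 and Derl3 at -0.73 ± 0.32) and the hypoxia and glycolysis list (0.00871, or 0.344 without PBS OIL replicate 2) lay lower. The adjusted p of the mitochondrial list was 0.954 with an estimated correlation, and that of the other 3 was 0.924. The 12 genes named in every comparison (Cdkn1a, Mdm2, Top2a, Top2b, Mki67, Esr1, Pgr, Ltf, Igf1, Greb1, Ihh and Areg) all failed to pass under OIL.

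Under E2, 3162 genes rose with DOX and 3196 fell, 41.04% of those tested. At least 2-fold changes were mostly losses, with 432 genes higher and 1374 lower. The largest rises were in Kcnh1, a voltage-gated potassium channel (2.95 ± 0.46), Gjb2, the gap junction protein connexin 26 (2.7 ± 0.38), Tacr1, the substance P receptor (2.54 ± 0.52), Bdkrb1, a bradykinin receptor (2.53 ± 0.32), Tlr12 (2.51 ± 0.38) and Gfra1, a receptor subunit for GDNF (2.48 ± 0.41). The mean of Gjb2 went from 29.1 ± 11.9 to 190.1 ± 44.8 CPM. Among the falls Lrrtm1 (-5.17 ± 1) is a gene of synapse formation, and the other 5 belong to fat tissue: Cyp2e1 (-5.4 ± 1.62), the adipokine resistin Retn (-5.39 ± 1.36), adipsin Cfd (-5.3 ± 1.68), Car3 (-5.22 ± 1.61) and the lipid droplet protein Plin1 (-4.83 ± 1.44). Without PBS E2 replicate 1 the calls of Cyp2e1 (-3.28), Cfd (-3.18), Car3 (-3.56) and Plin1 (-2.88) ended; they also ended without DOX E2 replicate 1 (-4.88, -4.78, -4.68 and -4.31) or replicate 2 (-4.85, -4.75, -4.66 and -4.29). Cyp2e1, Retn, Cfd, Car3 and Plin1 were near or at 0 counts in DOX E2 replicates 1 and 2, so no fold is given without replicate 3.

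Of 30 measured endoplasmic reticulum chaperones and stress genes 24 rose and 1 fell (25 and 1 when adjusted over the list alone), with a median of 0.91. Hsp90b1 rose by 1.29 ± 0.12 (555.9 ± 62.7 to 1357 ± 154.3 CPM), Pdia4 by 1.28 ± 0.12, the lectin chaperone Calr by 1.06 ± 0.12 and Pdia3 by 0.86 ± 0.08. Members of other biosynthetic lists rose. In ribosome biogenesis 15 of 30 members rose and 0 fell (15 and 0 when adjusted over the list alone), with nucleophosmin Npm1 at 0.74 ± 0.12. Among nuclear oxidative phosphorylation genes 17 of 30 rose and 0 fell (18 and 0 when adjusted over the list alone). In cholesterol biosynthesis 9 of 24 rose and 0 fell (9 and 0 when adjusted over the list alone), with Lss at 0.8 ± 0.11. Camera with the preset correlation called all 4 lists higher (adjusted p = 2.22e-12, 0.000357, 2.87e-05 and 0.0102). The adjusted p with an estimated correlation was 0.558, 0.918, 0.842 and 0.842. Mitochondrially encoded genes rose in 6 of 13 members and fell in 0, also when adjusted over the list alone (preset adjusted p = 0.0277, or 0.0504 without PBS E2 replicate 2 and 0.0889 without DOX E2 replicate 1; adjusted p = 0.918 with an estimated correlation).

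Of 19 measured clock genes 13 fell and 2 rose, also when adjusted over the list alone. The output regulators Dbp (-3.21 ± 0.28, from 89.4 ± 28.6 to 9.59 ± 1.07 CPM) and Tef (-1.82 ± 0.16), the repressor Nr1d1 (-2.97 ± 0.29) and Per3 (-2 ± 0.2) led the list, whose preset adjusted p was 0.000101 and whose adjusted p was 0.558 with an estimated correlation. Clock genes also change with the hour of day, and the labels do not give the hour of collection. Among 38 progesterone-induced genes 6 rose and 8 fell, also when adjusted over the list alone, with Tsc22d3 (-1.55 ± 0.16), Per1 (-1.88 ± 0.23) and Zbtb16 (-1.7 ± 0.3) lower and Sgk1 (1.14 ± 0.24) higher. As a list these did not pass (preset adjusted p = 0.834, and adjusted p = 0.961 with an estimated correlation). Without PBS E2 replicate 2 the sign of the test turned (0.902). Of steroid receptors and cofactors 0 of 19 rose and 10 fell over all genes, 3 and 10 when adjusted over the list alone (preset adjusted p = 0.112, adjusted p = 0.842 with an estimated correlation; 0.0479 with the preset correlation without PBS E2 replicate 1). The glucocorticoid receptor Nr3c1 (-0.79 ± 0.13), the mineralocorticoid receptor Nr3c2 (-1.32 ± 0.23) and the membrane estrogen receptor Gpr30 (-2.57 ± 0.48) fell, as did Esr1, the main nuclear estrogen receptor of the uterus (-0.7 ± 0.15, 695.3 ± 163.7 to 427.2 ± 68.4 CPM).

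Among the uterine estrogen-induced genes 13 of 41 rose with DOX under E2 and 2 fell (11 and 2 when adjusted over the list alone). Of all tested genes 41.04% were called there, so the number of members called does not set this list apart. Padi2, an arginine deiminase, rose by 2.21 ± 0.3, the metallothionein Mt2 by 1.43 ± 0.22, lipocalin Lcn2 by 1.76 ± 0.34, Igf1 by 0.79 ± 0.22 and Greb1 by 0.52 ± 0.18. The list had a preset adjusted p of 0.0287, which became 0.0518 without PBS E2 replicate 2, and an adjusted p of 0.842 with an estimated correlation. Without PBS E2 replicate 2 the Igf1 call ended (0.61, adjusted p = 0.0502), and the Greb1 call ended without PBS E2 replicate 2 (0.35) or 3 (0.48) and without DOX E2 replicate 1 (0.46) or 3 (0.52). Areg, encoding amphiregulin, rose from 4 to 20 counts summed over 3 libraries. That call ended in 4 of the 6 fits that left out 1 library (without PBS E2 replicate 2 at 2.09 or 3 at 2.08, or DOX E2 replicate 1 at 2.12 or 3 at 2.56). Without PBS E2 replicate 1, which holds the 4 counts, no fold is given. Epithelial cornified envelope genes rose in 7 of 18 members, with Tgm1 at 1.43 ± 0.27 and Lor at 1.22 ± 0.33, while periplakin Ppl fell (-1.25 ± 0.1), the 1 member lower. The same 7 and 1 passed when adjusted over the list alone (preset adjusted p = 0.0287; adjusted p = 0.842 with an estimated correlation; 0.053 with the preset correlation without DOX E2 replicate 2). Of 20 water and ion transport genes 7 rose and 2 fell, also when adjusted over the list alone, among them the chloride channel Cftr (1.46 ± 0.28) and the sodium channel subunit Scnn1b (1.94 ± 0.45), with a preset adjusted p of 0.241 and an adjusted p of 0.842 with an estimated correlation.

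Members of the p53 and interferon lists rose under E2. Of 30 p53 targets 12 rose and 2 fell, also when adjusted over the list alone. Ccng1 (1.27 ± 0.13), Zmat3 (1.02 ± 0.16), Rps27l (0.8 ± 0.12) and Mdm2 (0.48 ± 0.1) rose, and the detoxifying enzyme Ephx1 fell (-1.18 ± 0.15). Cdkn1a was at 0.7 ± 0.33 and did not pass (adjusted p = 0.0992), though it did without PBS E2 replicate 1 (1.02 ± 0.36). The list had a preset adjusted p of 0.0218 and an adjusted p of 0.842 with an estimated correlation. Of 34 interferon-stimulated genes 12 rose and 0 fell (10 and 0 when adjusted over the list alone), with Cxcl10 at 2.4 ± 0.46, the antiviral GTPases Mx1 and Mx2 at 2.29 ± 0.51 and 1.12 ± 0.27, and Oas1a at 1.55 ± 0.33. The list's preset adjusted p was 0.0561, with 0.0423 without PBS E2 replicate 3 and 0.000431 without DOX E2 replicate 1, and its adjusted p was 0.961 with an estimated correlation. Of 30 mitotic genes 0 passed by edgeR over all genes, and 0 when adjusted over the list alone (preset adjusted p = 0.223, or 0.0136 without PBS E2 replicate 2 and 0.00197 without DOX E2 replicate 2). Mki67, Top2b, Pgr (0.36 ± 0.19), Ltf and Ihh did not pass, and Top2a, the proliferation-linked target of DOX, was at 0.82 ± 0.37 (adjusted p = 0.0858; 1.16 ± 0.4 and passing without PBS E2 replicate 2, 1.14 ± 0.34 and passing without DOX E2 replicate 2).

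Of 21 adipocyte markers 17 fell and 0 rose (19 and 0 when adjusted over the list alone), with a median of -3.62. The mean log2 CPM of the list was 4.27 to 7.32 in the PBS E2 libraries and 1.16 to 3.94 in the DOX E2 libraries. Slc2a4, the insulin-responsive glucose transporter, was at -2 ± 0.33, Plin4 at -3.62 ± 0.65 and Scd1 at -3.38 ± 0.75. Without PBS E2 replicate 1 the last 2 were at -2.27 and -2.12. The list had a preset adjusted p of 1.61e-05 and an adjusted p of 0.842 with an estimated correlation. With the adipocyte score as a covariate, a setting added after the data were seen, the count of genes called for DOX under E2 went from 6358 to 4019. Of 10 oviduct and ciliated cell markers 5 fell and 0 rose, also when adjusted over the list alone, with Ccdc39 at -2.2 ± 0.19 and Wdr96 at -3.3 ± 0.62 (preset adjusted p = 0.052, or 0.0423 without PBS E2 replicate 3; adjusted p = 0.756 with an estimated correlation). Rfx2, higher with DOX under OIL, was lower with DOX under E2, at 9.54 ± 0.821 against 33.4 ± 1.39 CPM. It was the 1 gene called in both comparisons.

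**Figure D2:**
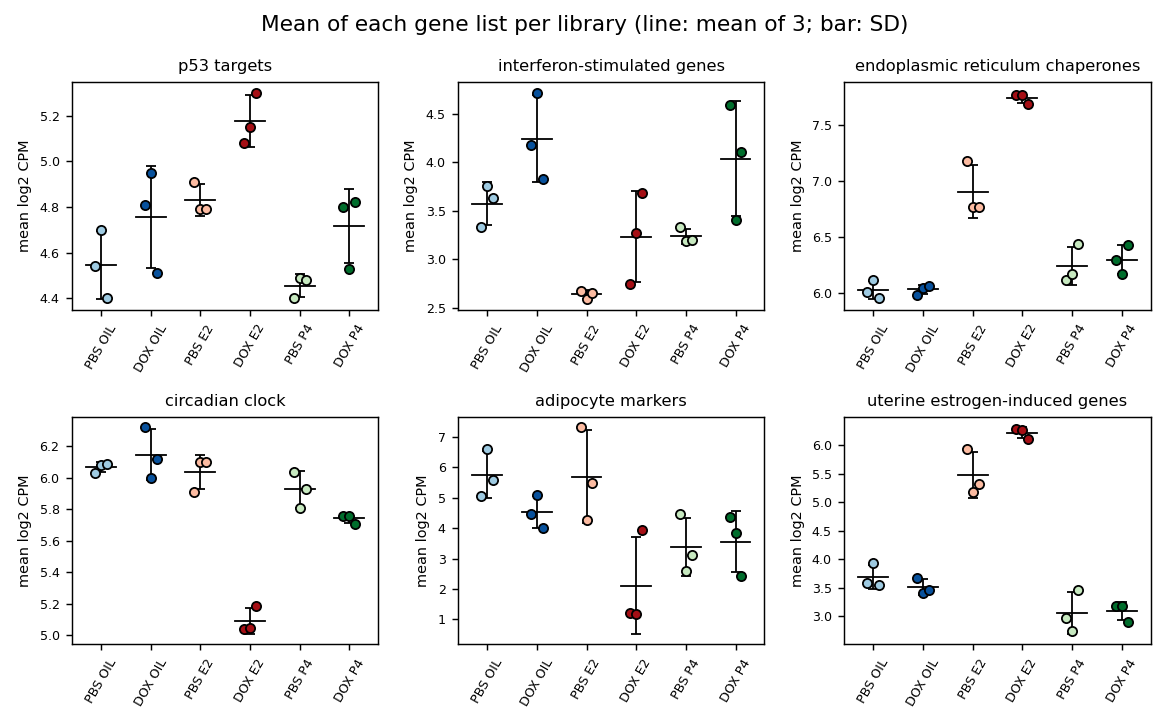
Mean log2 CPM of 6 gene lists on the y axis, 1 point per library in each of the 6 groups on the x axis; lines are means of 3 libraries and bars the SD. In the adipocyte panel the DOX E2 libraries span 1.16 to 3.94 and the PBS E2 libraries 4.27 to 7.32.

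Under P4, DOX changed 0 genes at the threshold by edgeR; 822 genes had an unadjusted p under 0.05, DESeq2 called 10 and limma voom 4. Of interferon-stimulated genes 0 of 34 passed over all genes by edgeR and 17 rose when adjusted over the list alone, with a median of 0.78, Oas3 at 2.83 ± 0.77, Cxcl10 at 1.57 ± 0.43, Ifit1 at 1.49 ± 0.41 and Oas1a at 1.16 ± 0.33 (preset adjusted p = 7.89e-24; adjusted p = 0.685 with an estimated correlation). Among p53 targets 0 of 30 passed over all genes and 5 rose when adjusted over the list alone, Cdkn1a at 1.43 ± 0.35 (17.4 ± 1.99 to 47.0 ± 17.7 CPM; DESeq2 gave an adjusted p of 0.0362), Trp53inp1 at 0.72 ± 0.17, Ccng1 at 0.52 ± 0.13 and Zmat3 at 0.58 ± 0.16, and Mdm2 was at 0.13 ± 0.1 (preset adjusted p = 6.27e-06; adjusted p = 0.685 with an estimated correlation). Fibrillar collagen and matrix genes had a median of 0.39 with 0 of 30 passing over all genes or over the list alone, Col3a1 at 0.83 ± 0.34 (preset adjusted p = 4.39e-10; adjusted p = 0.929 with an estimated correlation). Macrophage markers had a median of 0.4 with 0 of 22 passing either way, and Cx3cr1 at 1.36 ± 0.39 (preset adjusted p = 0.000666; adjusted p = 0.98 with an estimated correlation). The preset correlation called 7 more lists under P4, with 0 members passing over all genes or over the list alone. Inflammatory cytokines (adjusted p = 0.00236, or 0.0598 without PBS P4 replicate 2), replication-dependent histones (0.0342), neutrophil markers (0.0384), smooth muscle markers (0.0342) and mitochondrially encoded genes (0.0342) lay higher. Clock genes (0.00294, or 0.0948 without PBS P4 replicate 1) and luminal epithelium markers (0.0342) lay lower. The histone call ended without PBS P4 replicate 3 (0.424) or DOX P4 replicate 1 (0.115) or 3 (0.212). The neutrophil call ended without PBS P4 replicate 1 (0.051) or 2 (0.147) or DOX P4 replicate 2 (0.0555) or 3 (0.212). For smooth muscle it ended without PBS P4 replicate 3 (0.552) and turned sign without DOX P4 replicate 2 (0.717). The mitochondrial call ended without PBS P4 replicate 1 (0.138) or 3 (0.165) or DOX P4 replicate 2 (0.588). For luminal epithelium it ended without PBS P4 replicate 2 (0.0832) or DOX P4 replicate 1 (0.213) or 2 (0.109) and turned sign without PBS P4 replicate 3 (0.998). The adjusted p with an estimated correlation was 0.685 for clock genes, 0.929 for histones and 0.98 for the other 5 lists. The other genes named in every comparison did not pass: Top2a, Top2b, Mki67, Esr1, Pgr, Ltf, Igf1, Greb1, Ihh and Areg.

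**Figure D3:**
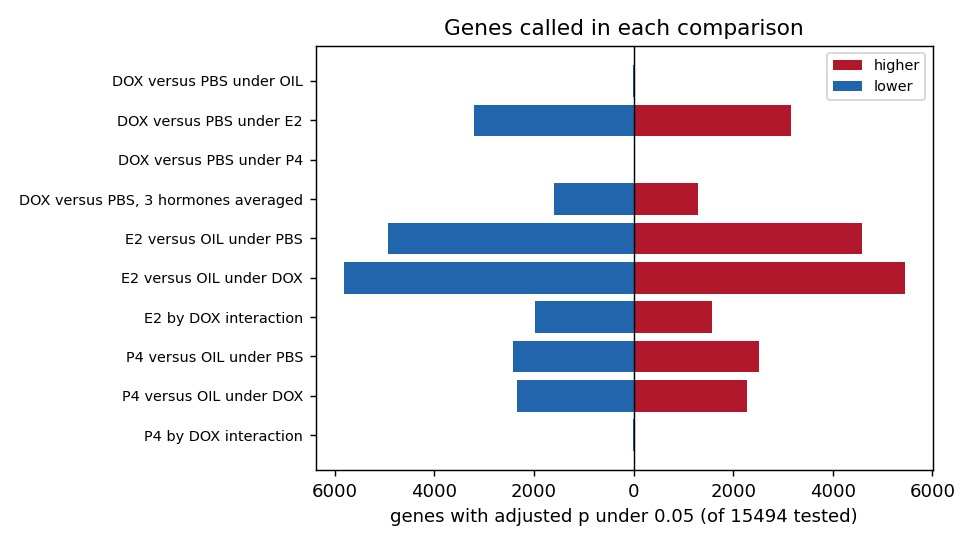
Genes with an adjusted p under 0.05 in each of the 10 comparisons, as bars of the number higher (right) and lower (left) of 15494 tested. DOX under E2 gave 3162 higher and 3196 lower, against 2 in all under OIL and 0 under P4.

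Averaged over the 3 hormone treatments, 9 libraries against 9, DOX raised 1294 genes and lowered 1593. Much of this count rests on E2, where DOX changed 6358 genes, against 2 under OIL and 0 under P4. Other splits of the libraries called up to 2439 genes where they kept the real E2 groups, and at most 3 where they did not. Mixing the E2 groups widens the spread estimated for all groups, so the latter does not tell what OIL and P4 added. The largest rises belonged to the interferon response, Cxcl10 (2.11 ± 0.26), Mx1 (1.77 ± 0.3) and the nucleic acid sensor Zbp1 (1.48 ± 0.26), and the largest falls to fat, leptin Lep (-2.37 ± 0.7), Retn (-2.32 ± 0.71) and Pck1 (-2.32 ± 0.5). Of 34 interferon-stimulated genes 22 rose and 0 fell (27 and 0 when adjusted over the list alone), and of 30 p53 targets 13 rose and 0 fell (14 and 1 when adjusted over the list alone), with Ccng1 at 0.78 ± 0.08, Zmat3 at 0.83 ± 0.09, Eda2r at 0.74 ± 0.11 and Cdkn1a at 1.06 ± 0.2 (adjusted p = 0.00285). Mdm2 rose by 0.22 ± 0.06. The preset adjusted p was 1.19e-11 for the interferon list and 3.58e-05 for the p53 list. The adjusted p with an estimated correlation was 0.926 and 0.704. In each fit that left out 1 library camera with the preset correlation also called 2 lists that moved under E2. These were endoplasmic reticulum chaperones (adjusted p of 2.24e-14 to 2.05e-11) and clock genes (6.86e-06 to 0.000156). With an estimated correlation 0 lists passed in this average. Adipocyte markers fell in 10 of 21 members and rose in 0 (0 higher and 18 lower when adjusted over the list alone; preset adjusted p = 8.86e-07, adjusted p = 0.926 with an estimated correlation). The Lep call ended in 8 of the 18 fits that left out 1 library and the Retn call in 9, with the smallest falls without PBS P4 replicate 1 for Lep (-1.61) and without PBS E2 replicate 1 for Retn (-1.75). Both were near or at 0 counts in DOX E2 replicates 1 and 2, so no fold is given without replicate 3. Mitochondrially encoded genes moved too, with 5 of 13 higher and 0 lower (7 and 0 when adjusted over the list alone; preset adjusted p = 0.000562, adjusted p = 0.926 with an estimated correlation). Their share of the counts was 3.465 ± 0.138% with PBS and 3.591 ± 0.1684% with DOX under OIL (SD), 2.789 ± 0.1374% and 3.123 ± 0.436% under E2, and 4.08 ± 0.27% and 4.491 ± 0.2616% under P4. Top2a, Top2b, Mki67, Esr1, Pgr, Ltf, Igf1, Greb1, Ihh and Areg did not pass. The count went from 2887 to 1909 without PBS P4 replicate 1, and limma voom called 4702.

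**Figure D4:**
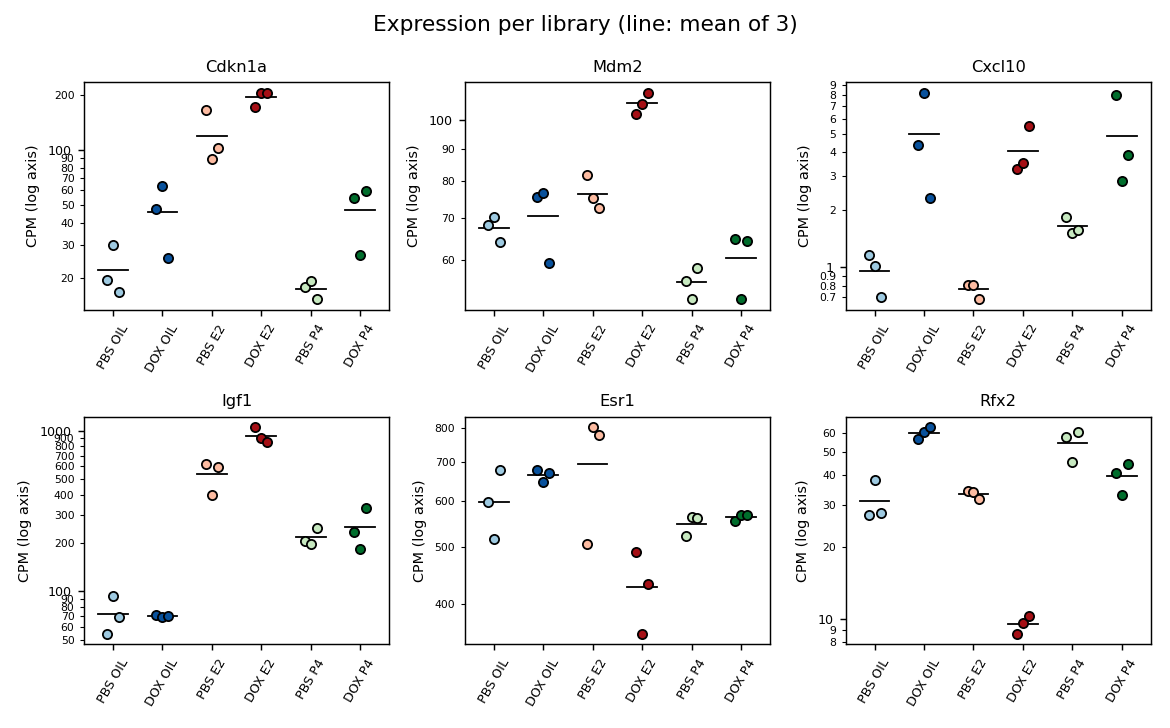
CPM on a log axis for 6 genes, 1 point per library in the 6 groups, with lines for the means of 3 libraries. Mean Cdkn1a was 22.1, 45.7, 119.2, 194.6, 17.4 and 47.0 CPM from left to right; Rfx2 was higher with DOX under OIL and lower with DOX under E2.

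The E2 response of the PBS arm is the background for these effects. E2 raised 4583 genes and lowered 4936, 1570 and 2135 of them at least 2-fold. The mitochondrial share of the counts was 3.465 ± 0.138% in the PBS OIL libraries and 2.789 ± 0.1374% in the PBS E2 libraries (SD). Their TMM factors were 1.075 ± 0.006 and 0.945 ± 0.042. The largest rises were Has1, a hyaluronan synthase (7.02 ± 0.64), the phosphatase Ptpn5 (7 ± 0.5), the neurotrophin receptor Ngfr (6.7 ± 0.5), the matrix protease Adamts4 (6.25 ± 0.78), the stress gene Gadd45g (5.41 ± 0.39) and Lrtm2 (5.28 ± 0.39). Falls were led by Pik3ip1, an inhibitor of PI3 kinase (-3.94 ± 0.28), the pro-apoptotic Bmf (-3.86 ± 0.26), Atp6v0d2 (-3.76 ± 0.96), Slco4c1 (-3.7 ± 0.45), the antiviral Rsad2 (-3.69 ± 0.37) and Gpnmb (-3.63 ± 0.85). Atp6v0d2 and Gpnmb rested on PBS OIL replicate 2, where Gpnmb was at 1213 CPM against 59.8 and 70.3 in the other 2 libraries. Without it the changes were -1.02 ± 0.57, no longer passing, and -0.84. Pgr (2.76 ± 0.21), Igf1 (2.89 ± 0.23), Greb1 (2.77 ± 0.19) and Cdkn1a (2.44 ± 0.35) rose and Mki67 fell (-1.19 ± 0.45), the last call ending without PBS OIL replicate 1 (-0.83) and without PBS E2 replicate 1 (-0.92) or 3 (-0.92) and at -1.91 without PBS E2 replicate 2. Mdm2, Top2a, Top2b, Ltf, Ihh, Areg and Esr1 (0.22 ± 0.15) did not pass. Without PBS E2 replicate 1 Esr1 passed at 0.41 ± 0.12.

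Members of growth-related lists rose with E2. All 30 ribosome biogenesis genes rose (30 when adjusted over the list alone), with Heatr1 at 2.66 ± 0.16 and Wdr43 at 2.21 ± 0.12. In cholesterol biosynthesis 17 of 24 rose and 2 fell, also when adjusted over the list alone, with Idi1 at 3.5 ± 0.19. Of 15 heat shock genes 13 rose and 0 fell (14 and 0 when adjusted over the list alone), with Hsp90aa1 at 2.38 ± 0.18. Endoplasmic reticulum chaperones rose in 25 of 30 members and fell in 1 (27 and 1 when adjusted over the list alone), with Atf4 at 2.2 ± 0.16. Immediate early genes rose in 20 of 25 members and fell in 1, and estrogen-induced genes in 26 of 41 and fell in 2, both also when adjusted over the list alone, with Fosl2 at 2.47 ± 0.17 and Inhbb at 5.21 ± 0.29. The preset adjusted p for these 6 lists was 5.68e-18, 6.25e-06, 3.74e-06, 3.74e-06, 3.31e-05 and 2.08e-05, and with an estimated correlation the adjusted p was 0.806, 0.877, 0.806, 0.999, 0.999 and 0.806. Interferon-stimulated genes went the other way, 2 higher and 20 lower of 34, also when adjusted over the list alone, with Cmpk2 at -1.84 ± 0.22 (preset adjusted p = 0.0074; adjusted p = 0.999 with an estimated correlation). Mitotic genes fell in 11 of 30 members and rose in 0 (6 and 0 when adjusted over the list alone), with Ndc80 at -1.48 ± 0.34. Its preset adjusted p of 0.0412 became 0.242 without PBS OIL replicate 1, 0.117 without PBS E2 replicate 1 and 0.159 without PBS E2 replicate 3, and the adjusted p was 0.999 with an estimated correlation. Adipocyte markers, 2 higher and 1 lower of 21 both ways of adjustment, did not pass as a list (preset adjusted p = 0.998, adjusted p = 0.999 with an estimated correlation).

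In the DOX arm E2 raised 5442 genes and lowered 5812, with 2515 and 3595 at least 2-fold. The TMM factors were 1.076 ± 0.023 in the DOX OIL libraries and 0.867 ± 0.023 in the DOX E2 libraries (SD). TMM takes most genes as unchanged, while 72.63% were called here and 61.44% in the PBS arm. Rises and falls with E2 are therefore relative to that scaling. Adamts4 (7.69 ± 0.85), Ptpn5 (7.6 ± 0.52) and the cornified envelope precursor Sprr2f (6.82 ± 1.2) rose furthest, and Lrrtm1 (-6.56 ± 0.99), the fructosamine kinase Fn3k (-6.52 ± 0.42) and the lactate receptor Gpr81 (-6.25 ± 0.72) fell furthest. Cornified envelope genes rose in 14 of 18 members and fell in 1, also when adjusted over the list alone, with Padi2 at 5.25 ± 0.35 and Tgm1 at 4.37 ± 0.31 (preset adjusted p = 0.0213; adjusted p = 0.783 with an estimated correlation). Of 21 adipocyte markers 2 rose and 3 fell, also when adjusted over the list alone, with a median of -2.14 (preset adjusted p = 0.16; adjusted p = 0.975 with an estimated correlation). Their mean log2 CPM was 1.16 to 3.94 in the DOX E2 libraries and 4.02 to 5.09 in the DOX OIL libraries. Pgr (3 ± 0.21), Igf1 (3.73 ± 0.24), Greb1 (3.45 ± 0.2), Cdkn1a (2.09 ± 0.34) and Mdm2 (0.59 ± 0.1) rose and Esr1 fell (-0.64 ± 0.15). Top2a (0.86 ± 0.37) and Ihh (1.05 ± 0.4) rose as well. Both calls ended in 4 of the 6 fits that left out 1 library, without DOX OIL replicate 2 (0.92 and 0.88), DOX OIL replicate 3 (0.63 and 0.86), DOX E2 replicate 1 (0.4 and 0.89), and DOX E2 replicate 3 for Top2a (0.88) or 2 for Ihh (0.97). Areg passed, with 20 counts against 1 in the DOX OIL libraries, too few for a fold. Top2b, Mki67 and Ltf did not pass. Between the arms 4158 genes were called higher and 4135 lower in both, where independence gives 1610 and 1852.

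The E2 responses of the arms were compared as a slope, DOX arm on PBS arm. Across the 9519 genes called under PBS, the regression through the origin had a slope of 1.2 ± 0.11 (jackknife SE over libraries), 96.45% of the genes kept their direction and 68.9% had a larger effect with DOX. Of 100 splits 22, the real one among them, gave a slope as far from 1. Those farthest from 1 held the real E2 groups with the arms exchanged. The genes chosen on the DOX arm gave 1.71 as the inverse of the PBS on DOX slope. On simulated data with a slope of 1.2 these ways of choosing genes returned 1.13 and 1.27. There, E2 effects under 2-fold were removed and genes were drawn independently. In these libraries 3705 of the 9519 genes changed at least 2-fold. The simulation therefore does not tell how much of the gap between 1.2 and 1.71 comes from the choice of genes.

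**Figure D5:**
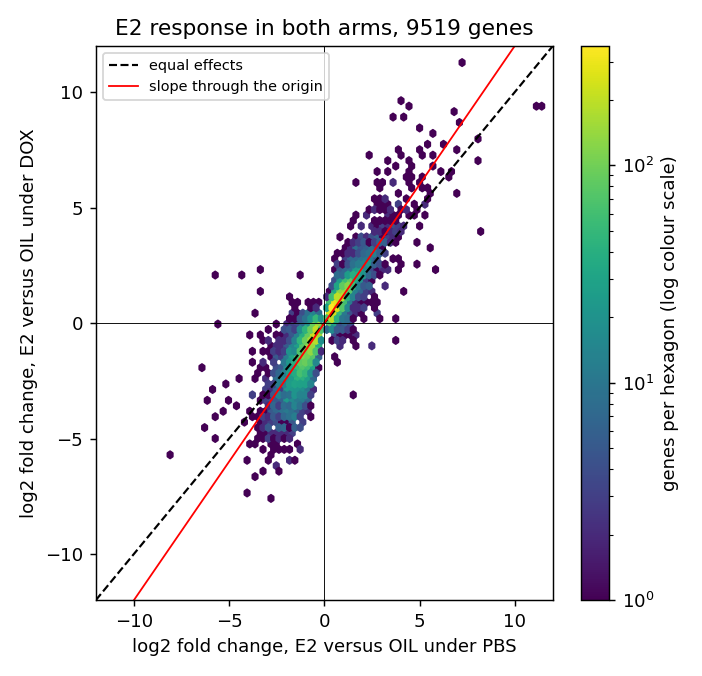
Log2 fold change for E2 versus OIL in the PBS arm (x axis) and in the DOX arm (y axis) for the 9519 genes called in the PBS arm, as counts of genes per hexagon on a log color scale. The red line is the slope of 1.2 through the origin and the dashed line marks equal effects.

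The difference between the E2 responses of the arms was itself tested, and 3553 genes passed, 1568 positive and 1985 negative. Of these, 2155 were called in both arms with a larger effect under DOX and 1029 were called under DOX alone, while 61 were called in opposite directions. Another 220 were called under PBS alone, 66 in both arms with a smaller effect under DOX, and 22 in neither arm. Limma voom called 5330. The positive differences were led by Spp1 (5.43 ± 1.85), Msr1 (3.61 ± 1.25), Cyp26b1, which degrades retinoic acid (3.43 ± 0.84), Kcnh1 (3.27 ± 0.63), Fabp5 (3.22 ± 1.07) and Slc15a3 (3.09 ± 1.05). Spp1, Msr1, Fabp5 and Slc15a3 are abundant in macrophages, and their values came from PBS OIL replicate 2 (319.1, 36.5, 75.3 and 26.1 CPM). Without it they were 0.17, 0.32, 0.71 and 0.71 and did not pass. The calls of Spp1 and Msr1 ended in 10 of the 12 fits that left out 1 library, and those of Fabp5 and Slc15a3 in 9. The negative differences were led by Lrrtm1 (-6.39 ± 1.22), Tmem45b (-4.47 ± 1.21; -3.35 and not passing without PBS E2 replicate 2), the sodium pump subunit Atp1a4 (-4.16 ± 0.48), Gpr81 (-3.78 ± 0.9) and Ypel4 (-3.74 ± 0.48). Esr1 passed at -0.86 ± 0.21 and Mdm2 at 0.41 ± 0.14. The Mdm2 call, at an adjusted p of 0.0491, ended in 8 of 12 fits that left out 1 library, with 0.3 without DOX OIL replicate 3 as the lowest value. Igf1 (0.84 ± 0.31) and Greb1 (0.69 ± 0.26) did not pass. Igf1 passed without PBS OIL replicate 1 (0.99) or PBS E2 replicate 1 (0.96), and Greb1 without PBS OIL replicate 2 (0.82) or PBS E2 replicate 1 (0.92). Cdkn1a, Top2a, Top2b, Mki67, Pgr, Ltf, Ihh and Areg did not pass.

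Members of the chaperone list had a larger E2 response with DOX, and clock genes a lower one, with the hour of collection again not given. Of all tested genes 22.93% passed in this interaction, the share against which the counts below are to be read. In the interaction 20 of 30 endoplasmic reticulum chaperones were positive and 0 negative (22 and 0 when adjusted over the list alone), with Pdia4 at 1.32 ± 0.17 and Hsp90b1 at 1.28 ± 0.17 (preset adjusted p = 1.95e-12; adjusted p = 0.527 with an estimated correlation). Of 19 clock genes 0 were positive and 12 negative (0 and 13 when adjusted over the list alone), with Dbp at -3.3 ± 0.37 and Nr1d1 at -3.1 ± 0.39 (preset adjusted p = 1.2e-05; adjusted p = 0.407 with an estimated correlation). Of 41 estrogen-induced genes 6 were positive and 1 negative, also when adjusted over the list alone, with Gjb2 at 2.92 ± 0.54, Lcn2 at 2.1 ± 0.48 and the calcitonin receptor partner Ramp3 at 1.81 ± 0.4 (preset adjusted p = 0.0055; adjusted p = 0.912 with an estimated correlation). Among 38 progesterone-induced genes 4 were positive and 5 negative (4 and 6 when adjusted over the list alone), with Sgk1 at 2.24 ± 0.34 and Zbtb16 at -2.98 ± 0.39. The median was -0.1 and the mean 0.02, and the list did not pass (preset adjusted p = 0.85; adjusted p = 0.959 with an estimated correlation). Smooth muscle markers were negative in 5 of 20 members and positive in 0, also when adjusted over the list alone, with Synm at -1.98 ± 0.41. The preset adjusted p of 0.03 became 0.0782 without PBS OIL replicate 1, 0.21 without DOX OIL replicate 3 and 0.0948 without PBS E2 replicate 1, and the adjusted p was 0.925 with an estimated correlation. Of 30 p53 targets 5 were positive and 3 negative, also when adjusted over the list alone, Ephx1 at -1.47 ± 0.21 (preset adjusted p = 0.256; adjusted p = 0.925 with an estimated correlation). Of 10 oviduct and ciliated cell markers 0 were positive and 4 negative, also when adjusted over the list alone, with Ccdc39 at -2.56 ± 0.25, Dnahc5 at -3.43 ± 0.71 and Tppp3 at -1.2 ± 0.29. The list had a preset adjusted p of 0.0306 and an adjusted p of 0.527 with an estimated correlation. It was 0.0889 without PBS OIL replicate 3, 0.0827 without PBS E2 replicate 1, 0.107 without PBS E2 replicate 2 and 0.0559 without DOX E2 replicate 3, with the preset correlation. Of 21 adipocyte markers 0 were positive and 3 negative (0 and 2 when adjusted over the list alone), no more than the share of all tested genes. Slc2a4 was at -1.97 ± 0.44. Their preset adjusted p of 0.0109 became 0.0604 without PBS OIL replicate 1 and 0.258 without PBS E2 replicate 1, and the adjusted p was 0.925 with an estimated correlation.

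P4 in the PBS arm raised 2509 genes and lowered 2421, 465 and 805 of them at least 2-fold. The largest rises were Lrp2, the endocytic receptor megalin (5.2 ± 0.68), Npl, which cleaves sialic acid (4.77 ± 0.26), the amino acid transporter Slc6a14 (4.57 ± 0.2), transthyretin Ttr (4.19 ± 0.45), Acot7 (3.77 ± 0.14) and Acta1 (3.74 ± 0.27). Clca3 (-5.82 ± 0.57) and lactoferrin Ltf (-4.22 ± 0.85) fell. Spp1 (-5.92 ± 1.37), Gpnmb (-4.21 ± 0.87) and Atp6v0d2 (-4.15 ± 0.98) fell as well, with values that came from PBS OIL replicate 2. Without it they were -0.68, -1.43 and -1.42, and of these Gpnmb alone passed. The call of Cyp2e1 (-4.06 ± 1.49) ended without PBS OIL replicate 2 (-3.2) or 3 (-4.19) and without PBS P4 replicate 2 (-3.57) or 3 (-3.81). Areg, an epithelial growth factor, had 0 counts in the 3 PBS OIL libraries and 617 in the 3 PBS P4 libraries (9.27 CPM), at least 202-fold higher against a floor of 3 counts over the group. Ihh, the epithelial hedgehog ligand (1.8 ± 0.41), and Igf1 (1.58 ± 0.22) rose, and Greb1 fell (-0.97 ± 0.19). The fall of Mdm2 (-0.29 ± 0.1) ended in 5 of the 6 fits that left out 1 library, all but PBS OIL replicate 3, at -0.33 to -0.24. Cdkn1a, Top2a, Top2b, Mki67, Esr1 and Pgr did not pass. The count was 3146 without PBS P4 replicate 3.

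Groups that moved with P4 in the PBS arm included progesterone-induced genes, of which 16 of 38 rose and 7 fell (16 and 8 when adjusted over the list alone), with the receptor chaperone Fkbp5 at 2.87 ± 0.19, Zbtb16 at 3.13 ± 0.27 and Hsd11b2 at 3.65 ± 0.33 (preset adjusted p = 0.00929; adjusted p = 0.713 with an estimated correlation). Of smooth muscle markers 14 of 20 rose and 0 fell (15 and 0 when adjusted over the list alone), with smooth muscle actin Acta2 at 1.11 ± 0.2 and Tpm2 at 1.34 ± 0.22 (preset adjusted p = 1.4e-05; adjusted p = 0.778 with an estimated correlation). Among oxidative phosphorylation genes 24 of 30 rose and 0 fell (25 and 0 when adjusted over the list alone), with Ndufa4 at 0.83 ± 0.12 (preset adjusted p = 2.42e-11; adjusted p = 0.713 with an estimated correlation). Of mitochondrially encoded genes 7 of 13 rose and 0 fell, also when adjusted over the list alone (preset adjusted p = 0.00109; adjusted p = 0.778 with an estimated correlation). Their share of the counts was 3.465 ± 0.138% in the PBS OIL libraries and 4.08 ± 0.27% in the PBS P4 libraries (SD). In the endometrial stroma list 10 of 18 rose and 1 fell (10 and 1 when adjusted over the list alone), with Mme at 2.03 ± 0.24 and Hoxa11 at 1.25 ± 0.2 (preset adjusted p = 0.00109; adjusted p = 0.713 with an estimated correlation). B and plasma cell markers went down: 0 of 14 rose and 7 fell (0 and 9 when adjusted over the list alone), with Derl3 at -3.22 ± 0.36 and Cd79b at -1.6 ± 0.41 (preset adjusted p = 0.00229; adjusted p = 0.778 with an estimated correlation). Of acute phase and antimicrobial genes 0 of 20 rose and 9 fell (0 and 10 when adjusted over the list alone), with Lcn2 at -2.57 ± 0.38. The preset adjusted p of 0.024 became 0.134 without PBS OIL replicate 2, and the adjusted p was 0.778 with an estimated correlation. Among water and ion transport genes 2 of 20 rose and 3 fell (2 and 3 when adjusted over the list alone), with Cftr at -2.86 ± 0.31 and Atp1b1 at 1.71 ± 0.2. The median was 0.03, the mean -0.58 and the test pointed down without passing (preset adjusted p = 0.977; adjusted p = 0.994 with an estimated correlation). Adipocyte markers moved beside these groups, where 0 of 21 rose and 9 fell (1 and 16 when adjusted over the list alone) (preset adjusted p = 0.00279; adjusted p = 0.792 with an estimated correlation).

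In the DOX arm P4 raised 2271 genes and lowered 2347, 452 and 600 of them at least 2-fold. Npl (4.62 ± 0.26), Slc6a14 (4.23 ± 0.19) and Lrp2 (3.79 ± 0.63) rose furthest, and Clca3 (-6 ± 0.54), the Wnt inhibitor Wif1 (-4.36 ± 0.72) and surfactant protein D, Sftpd (-4.35 ± 0.62), fell furthest. Areg passed, with 824 counts against 1 in the DOX OIL libraries, too few for a fold. Igf1 (1.83 ± 0.23) and Ihh (1.48 ± 0.4) rose, and Ltf (-3.27 ± 0.8; -2.16 without DOX OIL replicate 3) and Greb1 (-0.54 ± 0.19) fell. The Ihh call ended without DOX OIL replicate 2 (1.31) or 3 (1.29), and the Greb1 call in 5 of the 6 fits that left out 1 library, all but DOX P4 replicate 2, at -0.66 to -0.42. Cdkn1a, Mdm2, Top2a, Top2b, Mki67, Esr1 and Pgr did not pass. Of progesterone-induced genes 16 of 38 rose and 4 fell (17 and 5 when adjusted over the list alone) (preset adjusted p = 0.00255; adjusted p = 0.606 with an estimated correlation), and in the fibrillar collagen and matrix list 13 of 30 rose and 0 fell (13 and 0 when adjusted over the list alone), with Col6a2 at 1.6 ± 0.21 (preset adjusted p = 0.000322; adjusted p = 0.742 with an estimated correlation). Of clock genes 1 of 19 rose and 11 fell (1 and 11 when adjusted over the list alone) (preset adjusted p = 0.00831; adjusted p = 0.606 with an estimated correlation). Of 21 adipocyte markers 1 rose and 1 fell, also when adjusted over the list alone (preset adjusted p = 0.309; adjusted p = 0.909 with an estimated correlation). Between the arms 1727 genes were called higher and 1629 lower in both, where independence gives 367.8 and 366.7. The count was 3057 without DOX P4 replicate 3.

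The P4 by DOX interaction, the test of a different P4 response between the arms, called 1 gene, Rfx2 (-1.41 ± 0.2, adjusted p = 0.0477), whose mean was 54.5 CPM with PBS and 39.5 CPM with DOX under P4. Its call ended in 10 of the 12 fits that left out 1 library, all but PBS OIL replicate 2 and PBS P4 replicate 2, at -1.59 to -1.29. It also ended in 5 of 10 other settings, namely only the groups compared, the stricter filter, the replicate block, the adipocyte covariate and the GC and length correction. At an unadjusted p under 0.05 there were 525 genes, and DESeq2 called 2. Across the 4930 genes called for P4 under PBS, the slope of the DOX arm on the PBS arm was 0.73 ± 0.16 (jackknife SE over libraries), with 98.28% of the genes keeping their direction, and the genes chosen on the DOX arm gave 1.12. Of 100 splits 21 gave a slope as far from 1. In the fibrillar collagen and matrix list 0 of 30 members passed over all genes and 0 when adjusted over the list alone, with Col3a1 at 1.12 ± 0.48, which was 0.41 without PBS OIL replicate 2. The preset adjusted p of 2.07e-05 became 0.519 without that library, and the adjusted p was 0.882 with an estimated correlation. Of 21 adipocyte markers 0 passed over all genes or over the list alone, with a median of 1.85 (preset adjusted p = 0.000436, or 0.0698 without PBS OIL replicate 2; adjusted p = 0.882 with an estimated correlation). The 12 genes named in every comparison did not pass.

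The effects of DOX under OIL, E2 and P4 were compared across all genes. Their correlations across genes, which are not independent replicates, were 0.09 for OIL with E2, 0.06 for OIL with P4 and 0.06 for E2 with P4. By edgeR 0 genes were called in the same direction under a pair of hormones. With 2 genes called under OIL and 0 under P4 at most 2 could have been, so this count does not tell whether the effects are shared. Summed over the pairs of hormones, where a gene can count more than once, DESeq2 gave 10 shared calls and limma voom 3.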

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

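All patterns in this part were found in the comparisons and then examined on the same data. The bounds for the E2 response having gone further, for a loss of fat genes in every DOX animal, for fat carried with the tissue and for more immune cells were set after seeing those values or closely related ones. The bounds for the deepest library, the GC and length correction, the adipocyte covariate, single libraries and the other splits were set before those fits were made, with the counts of the comparisons known.

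The interaction of E2 with DOX stood out as a difference between the arms, with 3553 genes called. Among the genes named, Spp1 (5.43), Msr1 (3.61), Fabp5 (3.22) and Slc15a3 (3.09) owed their difference to PBS OIL replicate 2, without which they were 0.17, 0.32, 0.71 and 0.71. Cyp26b1 (3.43) and Kcnh1 (3.27) were higher in the E2 response of the DOX arm. Mdm2 (0.41) was higher too, a call that ended in 8 of 12 fits that left out 1 library and in 6 of 10 other settings. Lrrtm1 (-6.39), Tmem45b (-4.47, not passing without PBS E2 replicate 2), Atp1a4 (-4.16), Gpr81 (-3.78), Ypel4 (-3.74) and Esr1 (-0.86) were lower. In the interaction of P4 with DOX 1 gene differed, Rfx2 (-1.41), a call that ended in 10 of 12 fits that left out 1 library.

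DOX changed 6358 genes under E2, 2 under OIL and 0 under P4. Without the deepest library, PBS E2 replicate 1, 6822 genes were called; after the GC and length correction 6420; and with the adipocyte score as a covariate 4019, each above the 3000 set before those fits as too many for that explanation to be the whole cause. Of the 4335 genes called both for DOX under E2 and for E2 under PBS, 85.67% moved the same way. At an unadjusted p under 0.05 for DOX under E2 it was 83.49% of 5143 genes. Genes chosen in that way in 5 simulations with no DOX effect under E2, 455 to 519 of them, gave a mean of 36.35% and a highest of 39.96%, which allows for the shared PBS E2 libraries. A further advanced E2 response in the DOX E2 animals is a candidate explanation. Whether it came from DOX, or from the dose, the time of collection or the handling of E2, was not tested, since each E2 group is 1 set of 3 libraries and the labels give no times.

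Adipocyte genes were lower in the DOX libraries under E2. The score was lower in all DOX libraries than in all PBS libraries in 1 of 3 hormones. It was 4.02 to 5.09 with DOX against 5.07 to 6.6 with PBS under OIL, and 2.44 to 4.37 against 2.59 to 4.46 under P4. The ranges were much alike under P4 but barely overlapped under OIL. A bound of full separation, set after the scores were seen, therefore does not decide on a loss in every DOX animal. Within groups the members moved together from library to library, with a median correlation of 0.71 between pairs of member genes in their deviations across libraries, against at most 0.09 for random sets. That value lies between the bounds set for and against different amounts of fat carried with the tissue, so fat carried with the tissue and a change in fat of the DOX E2 animals cannot be told apart.

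Interferon-stimulated genes were higher in DOX libraries, 22 of 34 in the average over hormones. At least 16 members were called in each fit that left out 1 library, so no single library accounts for it. The highest median among the macrophage, T and NK cell and dendritic cell lists was 0.27 under OIL, 0.19 under E2 and 0.4 under P4, against 0.65, 0.64 and 0.78 for the interferon list. The 0.4 is that of macrophages, whose list had a preset adjusted p of 0.000666 under P4 (0.98 with an estimated correlation). Some medians lay below 0, as for dendritic cells (-0.45, quartiles -0.57 to -0.27) and T and NK cells (-0.27) under E2 and macrophages (-0.08, quartiles -1.02 to 0.28) under OIL. The last is set against PBS OIL replicate 2 among others, a library high in genes abundant in macrophages, so it carries little weight. As first set, on the average over hormones, the test had a highest median of 0.2, under the bound of 0.3, and read against more immune cells. It was then set for each hormone, after all these values were seen, and the 0.4 lies between the bounds. More macrophages under P4 and an interferon response in the DOX animals therefore cannot be told apart.

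Other splits of the same libraries were counted for each result. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05; the real split and the highest other called 2 and 1 genes for DOX under OIL (1 split as large, the real one). They called 6358 and 1 under E2 (1), 0 and 0 under P4 (10), 9519 and 2 for E2 under PBS (1), 11254 and 0 for E2 under DOX (1), 4930 and 0 for P4 under PBS (1) and 4618 and 0 for P4 under DOX (1). For DOX averaged over hormones 1 of 100 splits, the real one, gave 2887 genes. The highest other gave 2439 and was among the 10 that kept the real E2 groups, while those that did not reached at most 3. Splits that mixed the E2 groups put the difference between them into the spread estimated for all groups, so few calls were likely there. They do not tell what OIL and P4 added to the count. The splits that kept the real E2 groups are too few for a share under 0.05, so chance was not excluded for an effect shared over hormones. For the E2 by DOX interaction 8 of 100 splits gave as many genes, up to 4241, so chance was not excluded. The 7 others all kept the real E2 groups. Splits that mixed these groups called at most 1, with the same wider spread. With 9 other splits that kept these groups a share under 0.05 was hardly possible, so this test could not decide. For the P4 by DOX interaction 8 of 100 splits gave as many, at most 1. A slope as far from 1 came in 22 of 100 splits for E2 (0.2 against at most 0.44) and 21 of 100 for P4 (0.27 against at most 0.39). The real split is among them in each case. For E2 the splits at 0.41 to 0.44 kept the real E2 groups with the arms exchanged, so they hold the same difference between the arms. Splits that mixed the E2 groups reached at most 0.29. Chance was not excluded for either slope.

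List calls with the preset correlation were as many or more in most other splits. The number of splits with as many lists, with the real count and the highest other, was 92 of 100 for DOX averaged (8 and 22), 64 of 100 for the E2 by DOX interaction (12 and 24) and 98 of 100 for the P4 by DOX interaction (6 and 23), so chance was not excluded there. With 10 splits, too few for a share under 0.05, it was 9 for DOX under OIL (7 and 23), 7 under E2 (12 and 17), 7 under P4 (11 and 20), 9 for E2 under PBS (9 and 23), 10 for E2 under DOX (9 and 24), 4 for P4 under PBS (17 and 21) and 7 for P4 under DOX (16 and 23). What gives the many list calls in other splits was not tested.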

How the results depend on the processing

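The adipocyte covariate and the GC and length correction were added after the data were seen; the other alternatives were set beforehand. Of 243 alternative values of the leading results 204 stayed within 1.5 times the main count, or within the jackknife SE for the slopes. Sign and side of the threshold were kept by 5086 of 5375 values for named genes and 1146 of 1377 for gene lists. The causes of the changes below were not tested, except where a setting leaves out libraries or removes the adipocyte signal by construction.

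With DESeq2 the count was 20 for DOX under OIL (2 by edgeR), 10 under P4 (0), 2 for the P4 by DOX interaction (1) and 10 for the shared DOX calls (0). With limma voom it was 1 under OIL, 4 under P4, 4702 for DOX averaged (2887), 5330 for the E2 by DOX interaction (3553) and 3 for the shared calls. For DOX under OIL the adipocyte covariate and the GC and length correction gave 0 each. For the P4 by DOX interaction the stricter filter, the fit of only the groups compared, the adipocyte covariate and the GC and length correction gave 0 each. The adipocyte covariate gave 4019 genes for DOX under E2 (6358), and put Cyp2e1 at 0.16, Cfd at 0.3 and Plin1 at 0.46, a reversal for genes that make up or follow the score. Genes chosen on the DOX arm gave slopes of 1.71 for E2 (1.2) and 1.12 for P4 (0.73). Camera with the estimated correlation called 0 lists (107). The adipocyte list changed sign in E2 under PBS with DESeq2 size factors (0.996), and the water and ion transport list in P4 under PBS without a filter (0.961).

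The replicate block gave 0 genes for DOX under OIL and 0 for the P4 by DOX interaction, and no other leading count moved by over 1.5 times. The labels do not say that the numbers pair the libraries. In all groups together 7 of 18 libraries correlated best with one of their own number. The median correlation of deviations was -0.03 for the same number and -0.01 for others. Between DOX and PBS under OIL, however, same-number pairs were at 0.28, 0.36 and 0.09, against -0.31 to 0.04 for other pairs. A pairing is therefore not excluded in that comparison.

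Leaving out 1 library gave 0 to 2 genes for DOX under OIL, 1909 to 4055 for DOX averaged, 3146 to 4460 for P4 under PBS, 3057 to 3896 for P4 under DOX and 0 to 1 for the P4 by DOX interaction. Some list tests changed sign in at least 1 of these fits. The ranges of their adjusted p-values that follow cover all the fits, with and without a changed sign. They were 0.505 to 0.99 for the progesterone-induced genes in DOX under E2 and 0.481 to 0.959 in the E2 by DOX interaction. For DOX under P4 they were 7.09e-05 to 0.717 for smooth muscle and 5.34e-06 to 0.998 for luminal epithelium, where the sign turned at 0.717 and 0.998. The others were 0.337 to 0.97 for T and NK cells in DOX averaged and 0.492 to 0.99 for adipocytes in E2 under PBS. For interferon-stimulated genes in the E2 by DOX interaction the range was 0.0788 to 0.887. Mdm2 in DOX under OIL lay between 0 and 0.17.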

Other observations

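Under E2 with DOX, matrix-remodelling and glycolysis genes were called in both directions, in a comparison where 41.04% of all tested genes were called. Of matrix metalloproteinases and their inhibitors 3 of 19 rose and 6 fell (3 and 6 when adjusted over the list alone), with stromelysin 3, Mmp11, at -2.19 ± 0.23, Timp2 at -1.46 ± 0.17 and Mmp9 at -1.78 ± 0.34 (preset adjusted p = 0.582; adjusted p = 0.961 with an estimated correlation). In the hypoxia and glycolysis list 7 of 24 rose and 5 fell (8 and 5 when adjusted over the list alone), with the glycolytic enzyme Gapdh at 0.9 ± 0.14 and the mitophagy receptor Bnip3 at -2.07 ± 0.22; the median was 0.14, the mean -0.02 and the test did not pass (preset adjusted p = 0.694; adjusted p = 0.961 with an estimated correlation). Among mesothelium and peripheral nerve markers 1 of 13 rose and 5 fell (1 and 5 when adjusted over the list alone), with Wt1 at -0.64 ± 0.11; the preset adjusted p of 0.0287 became 0.0518 without PBS E2 replicate 2 and 0.101 without DOX E2 replicate 1, and the adjusted p was 0.842 with an estimated correlation. Of DNA replication genes 5 of 30 rose and 0 fell (3 and 0 when adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 at 1.4 ± 0.3; the preset adjusted p of 0.0442 ended past the threshold without PBS E2 replicate 1 (0.168) or 3 (0.148) and without DOX E2 replicate 1 (0.291) or 3 (0.0703), and the adjusted p was 0.961 with an estimated correlation.

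PBS OIL replicate 2 stood apart in genes abundant in macrophages. Gpnmb was at 1213 CPM there against 59.8 and 70.3 in the other PBS OIL libraries, Spp1 at 319.1 against 2.67 and 3.08, the integrin Itgax at 112.4 against 6.46 and 8.16, and Atp6v0d2 at 63.6 against 2.52 and 4.55.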
